A study of Mus musculus with 11 samples.

How the data were processed

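RNA sequencing was measured in 11 libraries of sorted J-RGC pools from postnatal mouse retina on a mixed C57BL/6 and CD1 background, 5 from control and 6 from Tbr1 KO animals. Per the labels' protocols, RNA came from pools of 100 sorted cells, and libraries were made with Smart-seq2 and Nextera XT and sequenced from a single end. The deposited values are raw read counts per gene symbol, 1 file per library. Per the submitters' processing notes, Trimmomatic 0.32, TopHat2 2.0.10 and HTSeq 0.6.1 were used with mm10, the GRCm38 build. The role of each tool, the gene annotation and the strand setting are not given in the sources used here. Smart-seq2 does not mark the strand, so overlapping genes on opposite strands cannot be told apart. PCR duplicates cannot be removed from these counts, since no molecular identifiers are described.

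The files held 24421 genes. Lines that name no gene were kept out of library sizes and tests. Reads assigned to genes were 60.1% to 63.9% of the reads listed in each library, reads in no feature 20.0% to 24.8%, ambiguous reads 1.31% to 1.47% and non-uniquely aligned reads 13.2% to 14.6%. The share in no feature was 21.7% ± 1.43 in control animals and 22.5% ± 0.591 in mutants (SD, n = 4; exact two-sided permutation p = 0.314).

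The labels tie libraries to separate animals, with 3 animals giving a pair of libraries each. Libraries of 1 animal are not independent, so their counts were summed and the animal was the replicate, 4 per genotype. Genes were filtered with filterByExpr, which left 13957, scaled with TMM and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are TMM-normalised, and log2 CPM of marker lists used a prior count of 0.5. The common biological coefficient of variation was 0.566. It was 0.556 between the pools of 1 animal and 0.630 between animals of 1 genotype. The fit was tested on simulated data with the real means and library sizes for 13630 genes in the 4 against 4 comparison. The simulated spread followed its trend over expression level, not each gene's own spread, and genes with the lowest levels were not changed. The fit called 30% of 100 genes changed 2-fold and 87% of 100 changed 4-fold, with 5 false calls, and made 0 calls when nothing was changed.

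Genes were named by a rule written before the data were examined, as were the gene lists, the design and most alternatives. The rule names Tbr1, Sorcs3, Cdh8 and Jam2, then up to 12 genes in each direction with the largest log2 fold change among those past the threshold, with at least 16 CPM in the higher genotype and no overlap between genotypes. Predicted genes and pseudogenes are counted and not named by it. From each gene list, up to 4 members are named, those past the threshold first. Hyi falls outside the rule as a pseudogene in the annotation.

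A total of 32 gene lists were fixed, and 30 had at least 3 tested members. They cover pan-RGC markers, RGC type transcription factors, other RGC types, amacrine, photoreceptor, bipolar, horizontal, Müller, non-neural and red blood cell markers, adhesion and guidance families, receptors, channels, vesicle, peptide and cytoskeletal genes, genes linked to Tbr1, stress, injury, cell cycle, metabolic, ribosomal and sex-linked genes. The list of mitochondrially encoded genes matched 0 genes in the files. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Library properties and list means were compared with exact two-sided permutation tests over animals, for which 0.0286 is the smallest possible p.

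Gene positions came from the GENCODE M21 annotation of GRCm38, which matched 13798 tested genes (98.9%) and 39 of the 40 changed ones. Alternatives were other units of replication, a replicate block, other scalings and filters, DESeq2 1.42.0, covariates, other thresholds and leaving out each animal. The plots were drawn with matplotlib 3.10.9. No sample was left out. Values of some single list members, and counts adjusted over the list alone that rest on them, are not reported here.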

Results

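The series profiled J-RGCs, a direction-selective type of retinal ganglion cell (RGC) that is known for expressing the adhesion molecule encoded by Jam2, from Tbr1 knockout (KO) and control (WT) mice. Tbr1 encodes a T-box transcription factor. The comparison asks which transcripts of this ganglion cell type depend on Tbr1. The cells carried a green fluorescent reporter and were sorted at postnatal day 4 to 5 into pools of 100 cells, and each of 11 pools gave 1 RNA sequencing library. The 5 control libraries came from 4 animals, here called control animals a (library 1), b (libraries 2 and 3), c (library 4) and d (library 5). The 6 mutant libraries came from 4 animals, mutant animals a (libraries 1 and 2), b (libraries 3 and 4), c (library 5) and d (library 6). Reads counted over genes ranged from 8609845 in control library 3 to 34718693 in control library 4, and 13897 to 15440 genes were detected per library. Counts were summed per animal, so every comparison set 4 animals against 4, with levels given as TMM-normalised CPM, a gene's counts scaled to a common library total. The reads carried no molecular identifiers, so the counting intervals and floors below cover counting error only.

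Tbr1 itself was still counted in every mutant library. Its level was 170 ± 16.5 CPM (SD, n = 4) in control animals and 120 ± 23.4 in mutants (SD, n = 4). All 4 mutant animals lay below all 4 control animals, with a log2 fold change of -0.50 ± 0.15 (SE). An exact two-sided permutation test of log2 CPM gave p = 0.0286, the smallest value that 4 against 4 animals allow, while the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes gave an adjusted p of 0.368. The labels do not say which part of Tbr1 (GRCm38 chromosome 2, 61802930 to 61814114) was removed, and counts per gene take in reads from any exons that remain, so this level does not check the genotype labels.

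Jam2 and Sorcs3, both fixed for reporting in advance, fell in the Tbr1 mutants. Jam2 (chromosome 16, 84774123 to 84825928) went from 528 ± 85.6 to 107 ± 21.5 CPM (SD, n = 4 per genotype), a log2 fold change of -2.31 ± 0.17 (SE). Sorcs3 (chromosome 19, 48206025 to 48805505), a sorting receptor of the VPS10 family, went from 142 ± 12.2 to 17.2 ± 6.19 CPM, a log2 fold change of -3.05 ± 0.25. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 6.41e-05 for Jam2 and 0.000187 for Sorcs3. Cdh8 (chromosome 8, 99024471 to 99416471), a type II cadherin, was at 124 ± 17.4 CPM in controls and 77.6 ± 16.5 in mutants, a log2 fold change of -0.67 ± 0.18. It overlaps the predicted gene Gm15679 on the opposite strand. Every mutant animal lay below every control animal for Cdh8, but its adjusted p over all genes was 0.272 by the same edgeR test with Benjamini-Hochberg adjustment. DESeq2, which called more genes than any other setting, was the only alternative to call Cdh8, at a Benjamini-Hochberg adjusted p of 0.0455. These 3 genes form a list taken from the published study of these samples, of which 2 fell over all genes and 3 were lower when adjusted over the list alone, and a list chosen on these samples is not independent evidence of its direction.

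**Figure D1:**
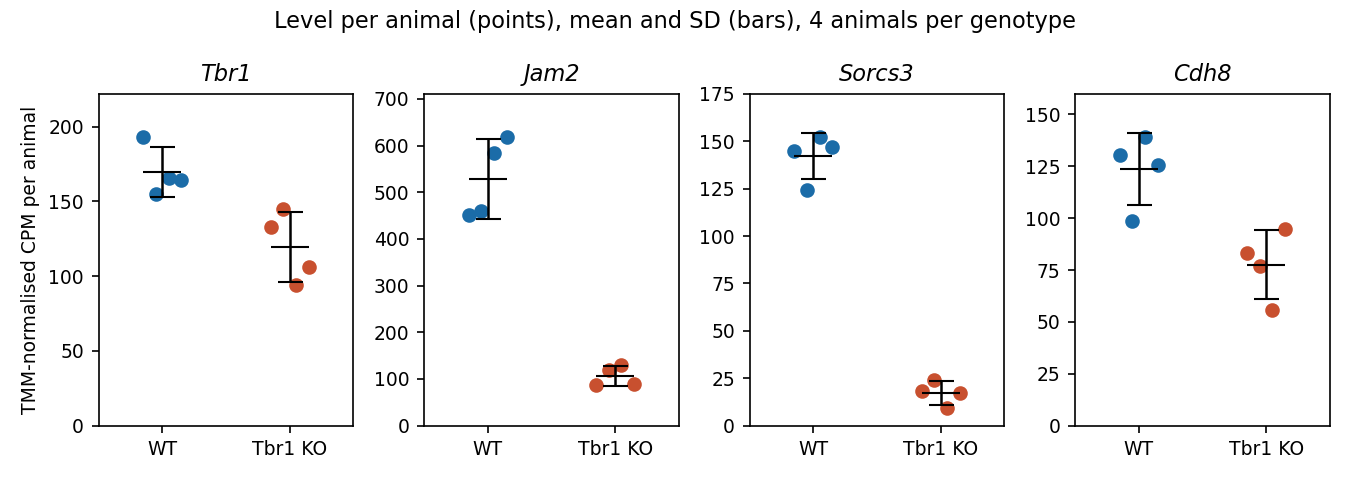
Level of Tbr1, Jam2, Sorcs3 and Cdh8 in each animal in TMM-normalised CPM (vertical axis, from 0) for 4 control and 4 Tbr1 KO animals. Points are animals, long bars are means and whiskers are SDs; for each of the 4 genes all mutant animals lie below all control animals.

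Across the transcriptome, 40 of 13957 tested genes changed between genotypes, of which 28 fell and 12 rose in the mutants. In all 40 the animals of one genotype lay above all animals of the other, and 31 differed by 2-fold or more. Over all tested genes, 706 (5.06%) showed no overlap between genotypes, where chance gives 2.86%. The calls came from the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and 990 genes had an unadjusted p under 0.05. The count was 18 without control animal b, 22 without mutant animal a, 17 without mutant animal b and 25 without mutant animal d, and DESeq2 called 156 genes.

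Among other genes that fell, Cap1, which encodes an actin-regulating protein, went from 257 ± 10.3 to 64.6 ± 12.6 CPM (SD, n = 4 per genotype), a log2 fold change of -1.99 ± 0.15 (SE). Tmeff2, a transmembrane protein, had a log2 fold change of -1.80 ± 0.19 from a control level of 232 ± 43.4 CPM. Pcdh19, a protocadherin, went from 70.2 ± 6.01 to 19.4 ± 4.28 CPM (-1.85 ± 0.20). Pmp22, a tetraspan membrane protein of myelin, went from 50.3 ± 10.9 to 9.22 ± 2.16 CPM (-2.45 ± 0.26). Adjusted p over these 4 genes was 6.41e-05 to 0.00137 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The secreted factor Fam19a4 went from 54.2 ± 7.66 to 5.86 ± 4.11 CPM, the lipid phosphatase Ppapdc1a from 46.2 ± 12.8 to 6.56 ± 3.81 CPM, and the cytokine Il1f9 from 16.8 ± 6.38 to 3.78 ± 0.605 CPM. Ecel1, an endopeptidase related to endothelin-converting enzyme, was at 33.6 ± 8.24 CPM in controls and was counted in 1 mutant animal only, at 1.07 CPM in mutant animal a. All 48 of its mutant counts came from library 1, and its fitted log2 fold change of -6.90 ± 1.19 (SE) was -13.24 without that animal, a value that depends on the prior count. Rad51b, of the homologous recombination machinery, had 2138 counts over the control animals and 1 count over the mutants, a ratio of 2741 with a 95% counting interval of 491 to 108300. Control animal d had 0.879 CPM of Rad51b against 12.4 to 29.3 in the other controls, and without mutant animal b no mutant count remained. The splicing factor Cwc22 went from 197 ± 77.4 to 28.0 ± 6.69 CPM, with control animal d at 85.8 CPM, and whether other gene copies share its reads was not tested, since no genome sequence was used. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave these 6 genes adjusted p of 0.00137 to 0.0443. Cap1 overlaps Ppt1 on the opposite strand, and the strand setting of the counting is not given in the sources used here. By the same edgeR test with Benjamini-Hochberg adjustment, Fam19a4 lost its call without control animal b (0.0567), Ppapdc1a without mutant animal a (0.0552) and Rad51b without mutant animal b (0.0592). Ecel1 kept its call only without mutant animal a and Il1f9 only without control animal d, with adjusted p of 0.0752 to 0.213 and 0.0925 to 0.167 in the 7 other fits of each by that edgeR test.

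Among genes that rose, Coch, which encodes the extracellular matrix protein cochlin, went from 4.10 ± 3.90 to 54.2 ± 8.80 CPM (SD, n = 4 per genotype), a log2 fold change of 3.74 ± 0.55 (SE). Control animal a was at 9.84 CPM of Coch against 1.14 to 2.73 in the other controls, and without that animal the log2 fold change was 4.64. Lypd6, a Ly6-family membrane protein, went from 69.7 ± 13.8 to 196 ± 18.3 CPM (1.49 ± 0.16). The splicing factor Srsf2 went from 206 ± 19.8 to 497 ± 142 CPM (1.27 ± 0.18), and Kcnip1, an accessory subunit of A-type potassium channels, from 124 ± 18.3 to 297 ± 52.8 CPM (1.26 ± 0.15). Adjusted p over these 4 genes was 0.00112 to 0.0113 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Smaller rises were measured for the hypoxia-response transcription factor Hif1a (0.99 ± 0.16), the secreted chaperone clusterin, Clu (0.77 ± 0.14), the lipid transfer protein Pitpnc1 (0.75 ± 0.12), the secreted protein Dkk3 (0.74 ± 0.14) and the neuronal calcium sensor Hpcal1 (0.72 ± 0.11), with edgeR Benjamini-Hochberg adjusted p of 0.0133 to 0.0495. Srsf2 overlaps Mettl23 and Mfsd11, and Kcnip1 overlaps Kcnmb1, on opposite strands. By the same edgeR test with Benjamini-Hochberg adjustment, Coch lost its call without control animal c (0.0534), control animal d (0.0627) or mutant animal b (0.0589), Clu lost it in all 8 fits that left out 1 animal (0.0839 to 0.200) and Dkk3 in all but that without control animal d (0.0671 to 0.209). Hif1a kept its call only without control animals a or c, Hpcal1 only without control animals a or c or mutant animal c, and Pitpnc1 only without control animals a or d or mutant animal c, with adjusted p up to 0.1002, 0.0707 and 0.0864 in the other fits by that edgeR test.

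**Figure D2:**
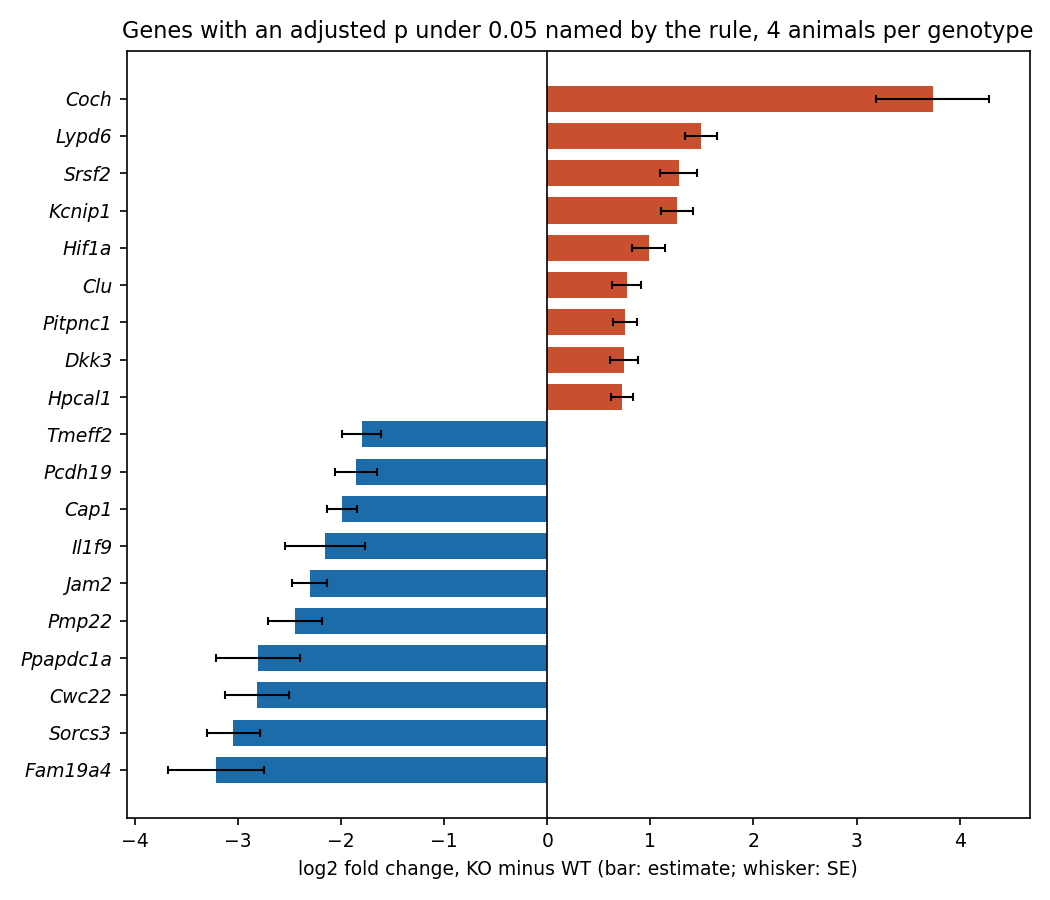
Log2 fold change, mutant minus control (horizontal axis), of the named genes that passed the test, from the edgeR fit over 4 control and 4 mutant animals. Bars are estimates and whiskers are SEs; Coch had the largest rise drawn (3.74) and Fam19a4 the largest fall drawn (-3.21), and Rad51b and Ecel1 are left out because their mutant counts come from a single library.

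Further genes past the threshold were picked out after their values were seen. Rgs4, a regulator of G-protein signalling, fell from 1961 ± 192 to 663 ± 282 CPM (SD, n = 4 per genotype), and Rnd3, a small GTPase, fell from 224 ± 18.8 to 81.5 ± 27.0 CPM. Tmem151b, a transmembrane protein, fell from 529 to 185 CPM, and 3 genes with clone names fell as well. Tacr1, the receptor for substance P, rose from 0.146 ± 0.0790 to 6.57 ± 1.38 CPM, and Hyi rose from 14.6 ± 0.887 to 36.9 ± 7.39 CPM. The adjusted p of Rgs4, Rnd3, Tmem151b, Tacr1 and Hyi was 0.0121, 0.00712, 0.00137, 0.0133 and 0.0313 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. By that edgeR test Rgs4 lost its call without control animals b (0.0663) or d (0.0518) or mutant animals a (0.0552) or c (0.0723), and Tacr1 without control animal b (0.0615) or mutant animals a (0.0552), b (0.0890) or d (0.0715). Hyi kept its call only without control animal a or mutant animal d, with edgeR adjusted p of 0.0891 to 0.126 in the other fits, and Rnd3 and Tmem151b kept theirs without any 1 animal.

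Of 18 protocadherins outside the gene clusters, Pcdh19 fell, and of 40 immunoglobulin superfamily recognition molecules, Jam2 fell. None of 12 classical and type II cadherins passed over all genes, and when adjusted over the list alone 4 were lower (Cdh4, Cdh8, Cdh6, Cdh20) and 2 higher (Cdh13, Cdh10). Of these, Cdh8 was named in the published study of these samples. Cdh4 had a log2 fold change of -0.62 ± 0.12 (SE) and Cdh13 one of 0.61 ± 0.15. Adjusted over the list alone, 4 immunoglobulin superfamily members were higher (Cadm1, Kirrel3, Mdga2, Lsamp) and 1 lower, and 2 protocadherins were lower. Cadm1 was at 363 ± 50.2 CPM in controls and 575 ± 82.7 in mutants (SD, n = 4 per genotype). None of 46 leucine-rich repeat and synaptic adhesion molecules passed over all genes, with 2 lower when adjusted over the list alone (Flrt2 at -1.20 ± 0.28 and Slitrk6 at -1.17 ± 0.29). Of the 5 VPS10 domain receptors, Sorcs3 fell and the other members gave log2 fold changes from -0.56 ± 0.23 (Sorcs1) to 0.31 ± 0.30 (Sorl1). The VPS10 list ranked low against other genes (camera adjusted p = 1.01e-05, Benjamini-Hochberg over the lists), with adjusted p = 0.0737 with an estimated correlation. It holds Sorcs3, which was named in the published study of these samples, so its rank is not independent evidence of a fall across the family.

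Guidance receptors gave no call over all genes. Among 26 semaphorins, plexins and neuropilins, 3 were higher (Sema6d, Plxna2, Nrp2) and 2 lower (Nrp1, Plxna3) when adjusted over the list alone. Nrp1 was at 83.8 ± 21.7 CPM in controls and 42.5 ± 9.34 in mutants (SD, n = 4 per genotype). Among 32 ephrins, netrins, slits and their receptors, Dcc was higher and Ephb6 lower when adjusted over the list alone, with log2 fold changes of 0.77 ± 0.18 and -0.96 ± 0.26 (SE).

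Among 51 voltage-gated channel genes, Kcnip1 and Kcna1 rose. Kcna1, a delayed-rectifier potassium channel subunit, had 0 counts in the control animals and 722 over the mutants, at least 187.7-fold higher against a floor of 3 counts over the group. When adjusted over the list alone, 4 channel genes were higher, with Scn1a and Kcnc2 added, and 1 was lower (Scn2b). None of 16 ionotropic glutamate receptors, 24 receptors for GABA, glycine and acetylcholine, 32 synaptic vesicle genes, 16 neuropeptides or 36 cytoskeletal genes passed over all genes. Gria1 and Sv2b were each higher when adjusted over their list alone, at log2 fold changes of 0.73 ± 0.20 and 1.19 ± 0.25 (SE). Kcna1 had an edgeR quasi-likelihood adjusted p of 0.0350 (Benjamini-Hochberg), and lost its call without control animal b, c or d or any 1 of the mutant animals (0.0679 to 0.155).

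Pan-RGC markers had list means of 8.36 ± 0.110 log2 CPM in controls and 8.26 ± 0.0961 in mutants (SD, n = 4; exact two-sided permutation p = 0.229). None of 22 passed over all genes, and Pou4f2, a POU-domain transcription factor of ganglion cells, was lower when adjusted over the list alone (282 ± 12.8 against 163 ± 37.7 CPM). None of 21 RGC type transcription factors passed over all genes, and Lmo4 was among those lower when adjusted over the list alone. Of 19 markers of other RGC types, Fam19a4 and Calb2 fell, and 4 were lower when adjusted over the list alone, with Igf1 and Cdh6 added. Calb2, which encodes the calcium-binding protein calretinin, went from 1269 ± 82.2 to 787 ± 115 CPM, a log2 fold change of -0.69 ± 0.11 (SE). The list of other RGC types ranked low against other genes (camera adjusted p = 0.00218, Benjamini-Hochberg over the lists), although 9 members had positive and 10 negative log2 fold changes. Its camera adjusted p was 0.0766 with an estimated correlation. Calb2 kept its edgeR call (Benjamini-Hochberg adjusted p = 0.0214) only without control animal a or mutant animal c, and had adjusted p of 0.0555 to 0.123 in the other fits.

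Markers of other retinal cells varied widely between animals of a genotype. All 18 tested photoreceptor markers had positive log2 fold changes, with a median of 1.83, and none passed over all genes. Their list mean was 0.40 ± 1.97 log2 CPM in controls and 2.47 ± 2.58 in mutants (SD, n = 4; exact two-sided permutation p = 0.257). All 7 bipolar markers (median 1.66) and all 5 horizontal cell markers (median 0.94) were positive as well, with none past the threshold over all genes and with Sept4 and Calb1 higher when adjusted over the horizontal list alone. Of 18 Müller glia and progenitor markers, Clu and Dkk3 rose, and adjusted over the list alone 2 were higher and 1 lower (Sfrp2). The camera adjusted p (Benjamini-Hochberg over the lists) was 0.000485 for photoreceptor, 0.0127 for bipolar, 0.00573 for horizontal and 0.00573 for Müller markers. In the same order it was adjusted p = 0.654, 0.353, 0.120 and 0.654 with an estimated correlation, and of the 7 lists called by camera the published-study list alone held its call in that setting (adjusted p = 0.000959 with an estimated correlation). Without mutant animal c the camera adjusted p was 0.0716 for photoreceptor, 0.357 for bipolar, 0.0603 for horizontal and 0.357 for Müller markers, and 3 lists were called. The bipolar list also lost its camera call without control animals a (0.418), b (0.0591) or c (0.121) or mutant animal d (0.0786), and the Müller list without control animals a (0.0648) or c (0.0786), as adjusted p.

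**Figure D3:**
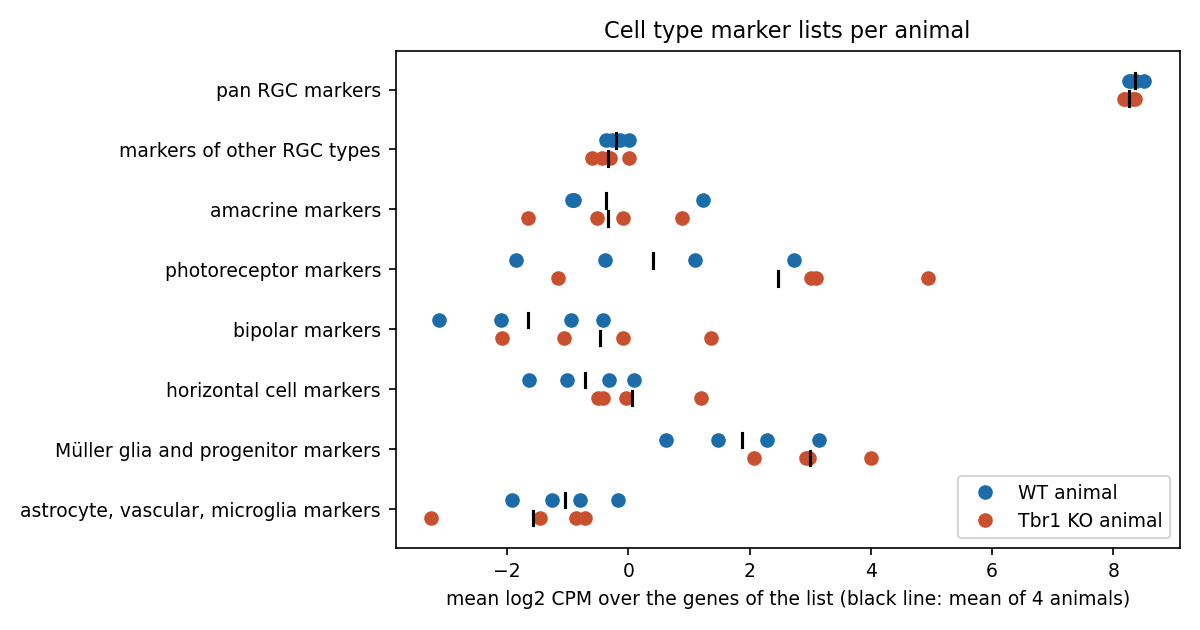
Mean log2 CPM over the genes of each cell type marker list (horizontal axis) in each of 4 control and 4 Tbr1 KO animals, with the mean of 4 animals as a black line. Pan-RGC markers lie near 8.36 in controls and 8.26 in mutants, while photoreceptor markers spread from -1.85 to 4.94 across animals.

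None of 10 amacrine markers passed over all genes. None of 13 astrocyte, vascular and microglia markers, 21 cell cycle genes, 23 immediate early genes, 40 oxidative phosphorylation genes, 51 cytosolic ribosomal protein genes or 4 sex-linked genes passed over all genes or adjusted over the list alone. Of 19 injury and apoptosis genes, Ecel1 fell. None of 14 genes linked to Tbr1 in other brain regions passed over all genes, with Cdh8 lower when adjusted over the list alone. Cdh8 was named in the published study of these samples, so its fall is not independent evidence for that list. Reln, Auts2 and Grin2b had log2 fold changes of 0.47 ± 0.15, 0.49 ± 0.20 and -0.32 ± 0.28 (SE). Of the red blood cell markers, Alas2 was tested, at 2.09 ± 1.57 CPM in controls and 2.88 ± 1.99 in mutants (SD, n = 4 per genotype). Total counts per animal (p = 0.229) and detected genes (p = 0.457) gave no detected difference between genotypes in exact two-sided permutation tests.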

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

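The split of animals was tested as planned, and the tests of the linked segment, of RNA from other cells, of Clu and Dkk3 and of other RGC types were chosen after the results were seen.

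In 76 groups of 4 animals, 5 held an animal far from the others, where chance gives about 1 in 20. In Rad51b and Ecel1 this follows from zeros in the other 3 animals, so these 2 cannot be set against that rate. Rad51b was at 0.0179 CPM (1 count) in mutant animal b and at 0 in the other mutants. Ecel1 was at 1.07 CPM in mutant animal a and at 0 in the other mutants. Fam19a4 was at 65.6 CPM in control animal d and at 49.9 to 51.2 in the other controls. Il1f9 was at 4.68 CPM in mutant animal c and at 3.41 to 3.54 in the other mutants. The amacrine marker mean was 1.24 log2 CPM in control animal c and -0.925 to -0.897 in the other controls.

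The genotype split gave 40 changed genes, and 1 of the 35 splits of the 8 animals into equal groups, the real one, gave as many. The highest count in another split was 0. A rank of 1 in 35 is the lowest that this design allows, so chance is made unlikely but is not excluded. Each other split mixes the genotypes, which widens the spread within its groups, so its count of 0 adds little to that rank.

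Lypd6, Rnd3 and Cwc22 lie within 20 Mb of Tbr1 on chromosome 2, 3 changed genes among 124 tested there against 0.35 expected. A candidate explanation is a chromosome segment that came with the mutant allele on the mixed background, and a one-sided Fisher's exact test gave p = 0.0256 after multiplication by the 5 regions tried. The window was seen before it was tested, so this p restates the pattern and leaves the segment a hypothesis. It also rests on that window, since by the same Fisher's exact test 0 of 69 genes within 10 Mb changed (p = 1), and neither 30 Mb (p = 0.0353) nor 40 Mb (p = 0.0319) passed after the same multiplication, nor chromosome 2 as a whole (4 genes against 3.06 expected, p = 0.366). An effect in cis of a segment linked to Tbr1 cannot apply to the 35 changed genes on other chromosomes, by their position alone. It stays open for Il1f9, 37.6 Mb from Tbr1, and for 1 changed gene without a known position. Effects of background variants on other chromosomes were not tested and stay open for the 35 genes. Effects in trans of a linked variant were not tested and stay open, as does an effect of Tbr1 on the 3 genes, since allele and genotype go together in this design.

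Photoreceptor, bipolar, horizontal and Müller marker lists ranked high in the mutants with camera at its preset correlation, but not with an estimated one (adjusted p = 0.654, 0.353, 0.120 and 0.654, Benjamini-Hochberg over the lists). RNA or cells of other retinal types may have entered the sorts, although sorting on the reporter would remove cells without it. Within genotypes, photoreceptor and bipolar means were compared over 8 animals (Pearson r = 0.839, exact permutation p = 0.0312, adjusted 0.0624 over both relations tried; Spearman rho = 0.786, p = 0.0451, adjusted 0.0902), with r = 0.572 without control animal a and mutant animal a. Photoreceptor and Müller means gave r = 0.639 (exact permutation p = 0.123; Spearman rho = 0.524, p = 0.205) and -0.00875 without these 2 animals. Neither relation passed after adjustment. An effect of genotype on the photoreceptor genes gave an exact permutation p = 0.257, with 3 of 4 mutant animals above the highest control, and these explanations cannot be told apart with 4 animals per genotype. The mean log2 difference of Clu and Dkk3 was 0.71 ± 0.12 (SE) with the mean of the other Müller markers in the model and 0.76 ± 0.10 without it. This argues only weakly against Müller RNA as their whole cause. The marker mean gives weakly counted members equal weight, so it may track Müller RNA poorly.

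Jam2 fell in the mutants, and a sort that held mostly other RGC types could lower it. The median log2 fold change of 19 markers of other RGC types was -0.47 ± 0.54 (bootstrap SE), with 9 positive. Spp1 was at 0 to 6.19 CPM in mutant animals and 0 to 2.38 in controls. Opn4 was at 3.63 to 5.75 CPM in controls, at 7.75 in mutant animal b and at 0.918 to 0.971 in the other mutants. These members go both ways, so a changed mix of types and an effect of Tbr1 on Jam2 cannot be told apart here.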

How the results depend on the processing

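The fits without the genes near Tbr1, of libraries 1 to 5 with no block and without the 4 animals with the highest photoreceptor markers were chosen after the data were seen; the other alternatives were planned.

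The named changed genes were chosen for no overlap between genotypes, so leaving out animals could hardly reverse their direction. Of 500 pairs of a named changed gene and an alternative, 398 kept the call and 102 lost it, with 0 reversed. All 21 named genes lost it without the 4 animals with the highest photoreceptor markers (control animal d and mutant animals b, c and d), with log2 fold changes in the same direction at 0.716 (Ecel1) to 1.40 times (Fam19a4) those of all 8 animals and a median of 1.09 times. In the other alternatives that tested them 10 of the 21, among them Jam2, Sorcs3, Cap1 and Tmeff2, kept it in each. Tbr1 never passed, with log2 fold changes from -0.61 to -0.35. Against 40 genes (12 higher, 28 lower), entering the 11 libraries as separate samples gave 84 (36 and 48), voom with the animal as a random block 76 (32 and 44), DESeq2 156 (74 and 82, with 61 adjusted p missing) and a stricter adjusted p of 0.01 gave 14 (2 and 12). At adjusted p under 0.1 there were 21 higher genes, with at least 10 CPM in 4 animals 22, and with detected genes as a covariate 7. Other scalings, no filter, the deepest library alone, marker and sex covariates and leaving out genes near Tbr1 gave 32 to 42 genes. Leaving out 1 animal gave 17 to 44 genes, 3 to 18 higher and 14 to 26 lower, with 18 without control animal b, 22 without mutant animal a, 17 without mutant animal b and 25 without mutant animal d. Without control animal a, with the fewest detected genes, there were 44. Without the 4 animals with the highest photoreceptor markers there was 1 gene (0 higher, 1 lower), not among the 40, and Lmo1 (-0.11 from 0.82) and Otx2 (-0.59 from 1.66), neither of them called, reversed. The edgeR fit then assumes that the lone mutant animal varies like the 3 controls. The marker covariate on all 8 animals gave 32 genes, with log2 fold changes of the 21 at 0.900 to 1.16 times. The sizes of these fold changes thus argue against photoreceptor RNA as their whole source, and the calls were lost with fewer animals. A stricter threshold can only lower the counts; for the other changes the cause was not tested.

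With the replicate number as a block, libraries 1 to 5 gave 42 genes, 32 of them shared, against 90 (38 and 52) on the same libraries with no block. Both fits entered libraries of 1 animal as separate samples and left out mutant animal d. Neither count can therefore be set beside that of the fit per animal. Same-numbered libraries had residual correlations of -0.114 to 0.0792, and 2 of 5 control libraries correlated best with the mutant library of their own number. Residuals were centred within each genotype, which makes correlations within a genotype negative on average. Of the libraries known to share an animal, mutant libraries 1 and 2 (-0.0438) had the highest correlation of all mutant pairs. Mutant libraries 3 and 4 (-0.0947) lay below mutant libraries 5 and 6 of different animals (-0.0681). Control libraries 2 and 3 (-0.332) did not stand out. The check thus missed 1 known sharing of an animal, so it could miss a pairing by number and leaves it open.

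Gene list calls went from 7 to 1 with an estimated correlation and to 4 with fry, and ranged from 3 (without mutant animal c) to 9 without 1 animal. In the simulated data, which left out the spread particular to each gene, 2-fold changes were called for 30% of the genes so changed.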

Other observations

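These values were picked out after the results were seen.

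Xist and Y-linked counts split the animals by sex. Control animal c and mutant animals b and c carried Y-linked genes at 123, 129 and 125 CPM, and the other 5 animals had at most 2.25. Xist was at 270 to 347 CPM in the other control animals and at 213 and 298 in mutant animals a and d.

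Control libraries 2 and 3, of 1 animal, had a residual correlation of -0.332, against -0.453 to 0.0422 for control libraries of different animals. Mutant libraries 1 and 2, of 1 animal, were at -0.0438, and mutant libraries 3 and 4, of another, at -0.0947. Mutant libraries of different animals were at -0.333 to -0.0681.

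Within the same window around Tbr1, Grb14 lies 3.11 Mb away, with a log2 fold change of 1.10 and an edgeR Benjamini-Hochberg adjusted p of 0.130.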
